A study of Mus musculus with 6 samples.

How the data were processed

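The series holds 6 Affymetrix mouse expression arrays of peritoneal macrophages elicited with thioglycollate, an irritant that draws macrophages into the abdominal cavity. The cells came from wild-type mice and from mice in which a Cre recombinase expressed from the lysozyme locus (LysM-Cre) deletes floxed Akirin2 in myeloid cells, called Akirin2 KO here. Cells were unstimulated or stimulated with lipopolysaccharide (LPS, a bacterial cell wall component) at 100 ng/ml for 2 or 4 h. Each of the 6 conditions had 1 array, so no condition has a replicate. Per the labels, the mice were of a mixed C57BL/6 and 129Sv background, and total RNA was amplified and biotin-labelled. The labels do not say how many mice gave each sample or whether the 3 samples of a genotype came from the same mice.

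The deposited values are log2 expression values per probe set, made with RMA per the submitters' processing notes. RMA corrects background, normalizes arrays by quantiles and summarises probes by median polish; its version and probe definition are not given in the sources used here. The deposited log2 values ran from 2.26 to 14.2 over 45101 probe sets. Array medians differed by at most 0.048, and sorted values deviated from the common quantiles by at most 0.13. Arrays give no read depth, and their number limits the precision.

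Probe sets were named from the platform annotation supplied with the series: 34958 had 1 gene symbol, 932 had several and 9211 were unnamed here. Of those with 1 symbol, 34754 matched a gene of the RefSeq annotation of GRCm38.p6 by gene number, and 0 symbols changed. The files name no genome build, so no coordinates are given and the annotation served only for names and for which genes neighbour each other. Each of 18194 genes was represented by its probe set with the highest mean. A floor kept the 13587 genes that reached, on at least 1 array, that array's median over all probe sets.

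Comparisons of single arrays have no test: genes were counted where the log2 difference was at least 1 (2-fold). The difference between the LPS responses of the genotypes was counted among genes with a mean induction over both genotypes of 2-fold or more, a choice that favours neither genotype. Tests used limma 3.58.1 in R 4.3.3 with lmFit, eBayes and Benjamini-Hochberg adjustment at 0.05. An additive fit had LPS time and genotype as terms, with 2 residual degrees of freedom and a prior worth 6.35. Its genotype p-values measure how constant a difference was over the 3 times, not the spread between animals. A further fit added the interaction of genotype with stimulation, with 1 residual degree of freedom and a prior worth 11.5. On simulated data for the 13587 genes, the genotype effect recovered 99.9% of genes changed by a log2 of 1, with a mean of 16.0 false calls over 10 runs. The interaction recovered 41.5% of genes at a log2 of 1 and 99.9% at 2, with a mean of 21.7 false calls. Simulated arrays without a genotype difference gave a mean of 8.40 genes that were 2-fold apart (3 to 12). The simulated noise was that of the additive fit, which leaves out any constant difference between mice or preparations. These simulations therefore do not show how far 2 independent preparations would differ. Simulated genotypes with equal responses gave a mean of 5.30 genes with a 2-fold response difference at 2 h among 318.2 induced genes, and 6.50 among 504.1 at 4 h.

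Gene lists (21 of functions, 10 of cell types and 4 of checks), the named-gene rule and the designs of the limma fits and counts were fixed before the data were examined; most tests of explanations in the closing section were chosen later, as stated there. A list's median was set against 10000 random lists of the same size matched on mean expression in 20 bins, and for response differences also on mean induction, then with only 3 bins of expression. The smallest pools drawn from held 10 genes at 2 h and 11 at 4 h, so these percentiles are rough. The percentile describes these arrays only, since genes are not replicates. On simulated lists of 20 genes, 5% of unshifted lists fell outside the middle 95 percentiles and 100% of lists shifted by 0.25 lay above the 97.5th percentile. The simulated genes varied independently of each other, so these shares do not carry over to lists whose members vary together. Named genes are Akirin2, Akirin1 and Lyz2; the 10 largest differences each way in the wild-type responses and between genotypes at each time; the 10 most reduced and most increased responses in KO among induced genes; the 10 largest effects each way past the threshold in each limma fit; and 2 to 4 members of a list. Which lists are described at more length was decided after their values were seen.

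Other settings, chosen at the same stage, were no floor, a floor at the 75th percentile, the mean of all probe sets, leaving out probe sets that may cross-hybridise, quantile normalization again, centring each array on the median of genes above the floor, size rules of 1.5-fold and 3-fold, choosing induced genes in 1 genotype, eBayes with trend and robust, an adjusted p of 0.1, leaving out each time, taking the LPS times together, and the other Akirin2 probe set. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 was used for the other steps. No column of the deposited values was left out.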

Results

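Gene expression was measured in thioglycollate-elicited peritoneal macrophages of 2 genotypes, wild-type and Akirin2 KO, at 0, 2 and 4 h of LPS, with 1 array for each of the 6 conditions. Akirin2 encodes a small nuclear protein, and the design asks how its loss in macrophages changes the transcriptional response to LPS. No condition has a replicate, so differences between single arrays carry no error and are given by size. Correlations between arrays over all probe sets lay between 0.958 and 0.989. The Y-linked gene Eif2s3y read between 8.13 and 8.50 on all 6 arrays.

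Akirin2 was lower in Akirin2 KO at all 3 times. Its log2 value was 7.43, 7.47 and 7.33 in wild-type and 5.18, 5.54 and 4.91 in KO at 0, 2 and 4 h. The KO level was 21.0%, 26.2% and 18.7% of wild-type at those times, a mean of 22.0% ± 3.89 (SD, n = 3 times). In the additive limma fit Akirin2 fell by 2.20 (SE 0.14, adjusted p = 0.000328). Its paralog Akirin1 differed by 0.092 (adjusted p = 0.784), and Lyz2, the lysozyme gene whose locus carries the Cre, by -0.12 (adjusted p = 0.704). The other Akirin2 probe set read near background, between 2.79 and 3.25, and did not separate the genotypes (-0.027, adjusted p = 0.951). Which part of the transcript each probe set reads was not analysed here.

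**Figure D1:**
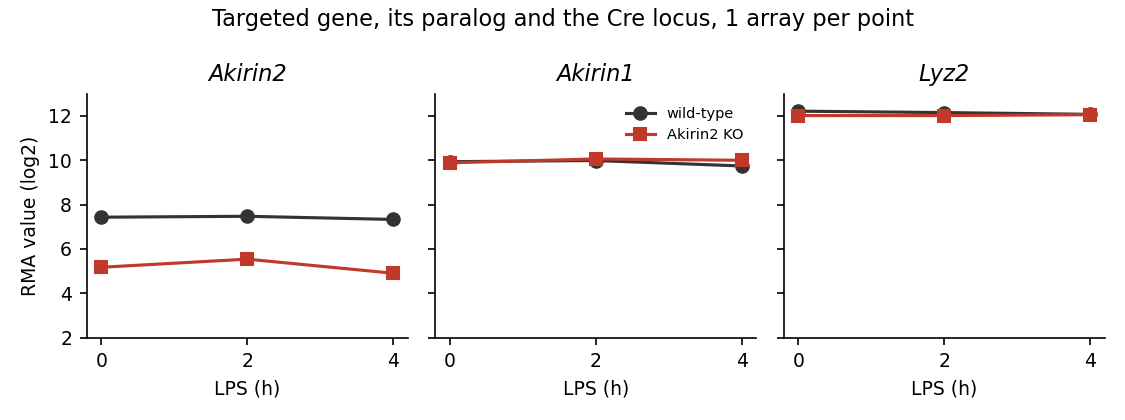
RMA values (log2) of Akirin2, Akirin1 and Lyz2 against hours of LPS, 1 array per point, for wild-type (circles) and Akirin2 KO (squares). Akirin2 lies between 4.91 and 5.54 in KO and between 7.33 and 7.47 in wild-type.

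Inflammatory genes were higher after LPS in wild-type macrophages at 2 h. The largest differences from 0 h at 2 h were those of Il1b (7.24), the neutrophil-attracting chemokines Cxcl1 (6.33), Cxcl3 (5.72) and Cxcl2 (5.08), Tnfsf9 (5.62), the prostaglandin synthase Ptgs2 (5.18), Tnf (5.16) and Ccl3 (4.96). At 4 h Ccl5 (5.79) and the cystine transporter Slc7a11 (5.06) were also among the top 10. The genes lowest relative to 0 h were Lpar6 (-3.27) and Rgs2 (-2.98) at 2 h. At 4 h they were the chemokine receptor gene Ccr2 (-3.82), Rgs2 (-3.66) and the chemokine receptor gene Cxcr4 (-3.50). By the 2-fold rule 307 genes were higher and 297 lower at 2 h, and 505 were higher and 646 lower at 4 h. The split depended on scaling: with each array centred, it was 406 higher and 191 lower at 2 h and 656 and 428 at 4 h.

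In Akirin2 KO the rule counted 332 genes higher and 123 lower at 2 h, and 553 higher and 336 lower at 4 h, or 460 and 456 with arrays centred. Of the genes higher in wild-type, 241 were also higher in KO at 2 h, where independent lists would share 7.50, and 376 at 4 h, where they would share 20.6. These responses share no array. Over both genotypes, limma called 538 genes higher and 393 lower at 2 h, and 1055 higher and 1034 lower at 4 h. All 15 measured NF-kB subunits and feedback regulators rose at both times. Of 37 measured interferon-stimulated genes, 10 rose at 2 h and 36 at 4 h, among them Ifit1 (5.08, SE 0.21, adjusted p = 4.61e-06 at 4 h). Of 21 proinflammatory cytokines, 9 rose at 2 h and 12 at 4 h, and of 20 chemokines 10 and 13 rose. At 4 h 3 chemokines fell, Ccl6, Ccl24 and Cxcl9. Of 10 targets of NRF2, a regulator of antioxidant genes, 9 rose at 4 h. Proteasome subunits counted 0 of 32 at 2 h and 12 at 4 h. Among genes that fell at 4 h were Fbxo32 (-3.54), Ccr2 (-3.39) and Rgs2 (-3.25).

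**Figure D2:**
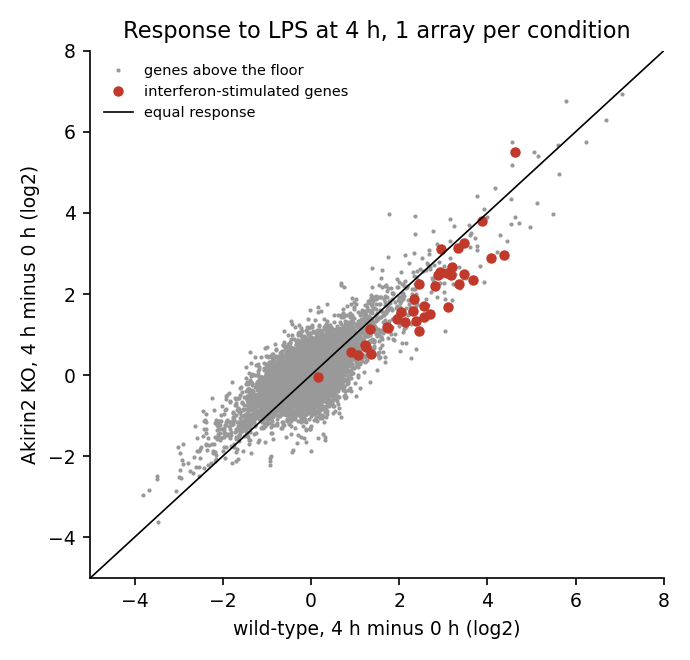
Difference between 4 h and 0 h of LPS (log2) in Akirin2 KO against that in wild-type, 1 point per gene above the floor, with interferon-stimulated genes marked and a line of equal response. Ifit1 lies above the line, and most interferon-stimulated genes lie below it, with a median response difference of -0.58.

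A constant difference between genotypes was seen for a small set of genes. Hal, the histidine ammonia-lyase gene, was the most reduced: it fell by 4.13 (SE 0.14, adjusted p = 1.2e-05). Lox, which encodes the collagen cross-linking enzyme lysyl oxidase, rose by 3.19 (SE 0.14, adjusted p = 4.96e-05). Mustn1 (2.85), Mamdc2 (2.80), Mgst2 (2.23), Bex1 (2.07), Bcat1 (2.00) and the integrin gene Itgb3 (1.95) also rose, and Ifi27l2a (-1.74), Cxcl14 (-1.69), Slfn1 (-1.65) and AW112010 (-1.52) fell. At 2-fold or more at all 3 times, 19 genes were higher and 18 lower in KO, where independent lists of the sizes found would share 0.0043 and 0.0045. These 3 comparisons share no array, but the 3 samples of a genotype may come from the same mice. A difference between mice or preparations would then recur at each time, so the overlap is not independent repetition. Mesothelial and fibroblast markers were also lower in KO, with a median of -0.62.

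The single times gave 106 genes higher and 156 lower in KO at 0 h, 66 and 63 at 2 h, and 113 and 84 at 4 h. With the probe sets of a gene averaged the counts were 36 and 66, 37 and 37, and 50 and 52. The splits at 0 h and 4 h turned with arrays centred (196 higher and 85 lower at 0 h, 75 and 125 at 4 h), and at 0 h also with quantile normalization again (145 and 115). In the additive fit limma called 121 genes higher and 144 lower over the 3 times. The unadjusted p was under 0.05 for 2091 genes. The count was 370 and 294 without the 0 h arrays, a fit that kept all 265 calls, and 72 and 86 without the 2 h arrays, which kept 140 of them. Without the 4 h arrays it was 122 and 151, of which 186 were among the 265. With eBayes set to trend and robust it was 419 and 464.

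Interferon-stimulated genes were lower in KO as a group. Of 37 measured, 15 fell and 0 rose (adjusted over the list alone, 30 fell). Of the 15, Xaf1 (-1.37) turned to 0.46 with probe sets averaged. Ifit1 fell by 1.77 (SE 0.17, adjusted p = 0.00354), Rtp4 by 1.60 (SE 0.14, adjusted p = 0.00199), Ifit2 by 1.42 (SE 0.20, adjusted p = 0.0146) and Oasl2 by 1.24 (SE 0.14, adjusted p = 0.00589). The transcription factor genes Irf7 (-0.77) and Irf1 (-0.82) also fell. Outside the list Ifi27l2a fell by 1.74, but Gbp2b rose by 1.92, while the listed Gbp2 was among the 15 that fell. The list's median difference was -0.37 at 0 h, -0.59 at 2 h and -1.03 at 4 h, each below all 10000 random lists. With arrays centred it was -0.21 at 0 h and -1.14 at 4 h. Over the 3 times the list stood at -0.72, beside -0.62 for mesothelial and fibroblast markers (-0.32 with probe sets averaged). Low percentiles were not particular to this list: over the 3 times, 14 of the 21 function lists lay below the 2.5th percentile and none at the matching high end. The 3′ to 5′ difference of Actb, a sign of RNA quality, was also higher in KO, at 4.64, 4.50 and 4.36 against 4.22, 4.16 and 4.09 in wild-type, and that of Gapdh was 4.34, 4.52 and 4.44 against 4.33, 4.33 and 4.42. Ifnb1 itself stayed near background on all arrays.

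**Figure D3:**
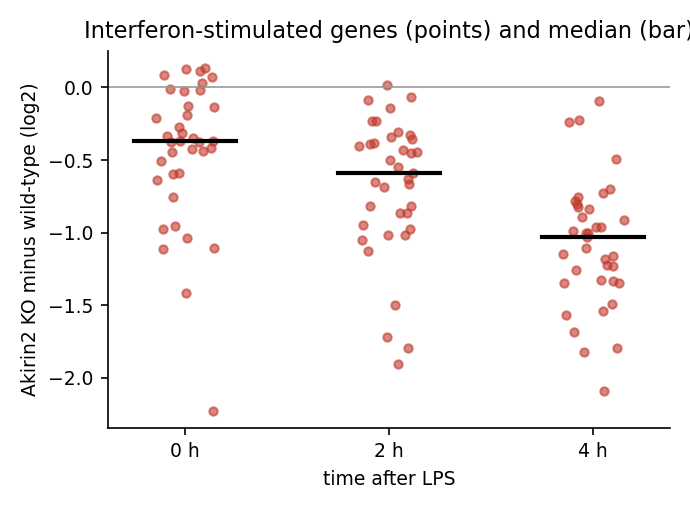
Akirin2 KO minus wild-type (log2) for each measured interferon-stimulated gene at 0, 2 and 4 h of LPS, 1 point per gene and 1 array per condition, with the median as a bar. The medians are -0.37, -0.59 and -1.03.

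Genes of cholesterol synthesis and transport were lower as well. Of 16 measured, 6 fell and 1 rose (adjusted over the list alone, 9 and 3). Cyp51 fell by 1.28, Apoe by 1.13, Fdft1 by 0.88 and Sc5d by 0.73, and the sterol-sensing receptor gene Nr1h3 rose by 0.74. The median over the 3 times was -0.41, below all random lists, again beside the mesothelial and fibroblast markers (-0.62, or -0.32 with probe sets averaged). The Actb difference was again higher in KO (4.64, 4.50 and 4.36 against 4.22, 4.16 and 4.09). That of Gapdh was 4.34, 4.52 and 4.44 in KO against 4.33, 4.33 and 4.42.

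Among 21 cytokines 3 fell, Tnfsf9 (-0.88), Il1b (-0.82) and Il1a (-0.72), and 0 rose (adjusted over the list alone, 6 and 1). Among 20 chemokines Cxcl13 (-1.27), Ccl24 (-1.13) and Cxcl10 (-1.01) fell (adjusted over the list alone, 7 fell and 2 rose). The medians over the 3 times were -0.20 for each list, at percentile 0.03 for cytokines and below all random lists for chemokines. Il6 was lower in KO by 1.58 at 2 h and 1.73 at 4 h, with an adjusted p of 0.0976 over the 3 times. Tnf differed by -0.56 (adjusted p = 0.0724). The same marker and Actb differences stand beside these lists. The NF-kB list had 0 calls between genotypes in limma and a median of -0.21 at percentile 0.26, and TLR signalling components 0 calls and a median of -0.22, below all random lists (-0.11 with probe sets averaged); adjusted over the list alone, each also had 0. Of 22 immediate-early genes Ier3 (-1.08) and Egr1 (-1.06) fell (adjusted over the list alone, 5 fell and 4 rose), and of 21 antigen presentation genes H2-DMa (-0.85) and Cd40 (-0.74) fell (adjusted over the list alone, 6).

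Markers of cell types were set beside these differences. Mesothelial and fibroblast markers had a median of -0.62 over the 3 times, below all random lists, and of 9 measured Col1a2 fell by 0.83 (adjusted over the list alone, 6 fell). Of 17 macrophage markers C1qa (-1.08), Fcgr1 (-0.89) and C1qc (-0.71) fell, with a list median of -0.12 at percentile 1.52 (adjusted over the list alone, 4 fell). Resident peritoneal macrophage markers had a median of -0.21, which was -0.61 at 0 h, -0.26 at 2 h and -0.026 at 4 h, and of 9 measured Cxcl13 fell (adjusted over the list alone, 2). Of 6 neutrophil markers 0 passed (adjusted over the list alone, 2 fell), with a median of -0.19, or -0.061 with no floor and -0.33 with the higher floor. The medians of B cell, T and NK cell, and mast cell markers were -0.025, -0.020 and 0.032, and the mast cell median was -0.17 with the higher floor. Of 5 T and NK cell markers Cd28 rose by 1.19, which is also the list's median with the higher floor, where Cd28 alone remains. Eosinophil, dendritic and erythroid lists had 2, 2 and 1 measured genes.

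The last comparison asks whether the LPS response itself differed. Relative to wild-type, the induction of Ereg, an epidermal growth factor family ligand, was lower in KO by 1.93 at 2 h and 1.95 at 4 h. The response difference of Il6 was -1.50 and -1.65, that of Ccl3 -1.33 and -1.51, and that of the NF-kB subunit gene Rel -1.26 and -1.43. For Ccl3, Rel and Ereg the KO array was higher at 0 h, by 1.12, 0.70 and 0.59. Induction was larger in KO for Plet1 (1.21 at 2 h, 2.20 at 4 h) and Mmp13 (1.55 and 1.58). Of 310 genes induced at 2 h, 14 were at least 2-fold less and 4 at least 2-fold more induced in KO, and 7 of the 14 were higher in KO at 0 h by at least 0.5. Of 485 induced at 4 h, 35 were less and 10 more induced, with 13 of the 35 higher in KO at 0 h by at least 0.5. At the LPS time itself, 10 of the 14 and 29 of the 35 were lower in KO by at least 0.5. With arrays centred the counts were 66 and 6. Choosing induced genes in KO alone turned the counts to 9 less and 13 more at 2 h, and 24 less and 44 more at 4 h. Choosing them in wild-type alone gave 17 less and 2 more at 2 h, and 43 less and 6 more at 4 h. A choice in 1 genotype favours a larger response in that genotype by construction. Simulated genotypes with equal responses gave, among induced genes and in either direction, a mean of 5.30 at 2 h (1 to 8) and 6.50 at 4 h (4 to 9). Over all 13587 genes, 236 had a 2-fold response difference at 2 h and 427 at 4 h, against simulated means of 92.4 and 91.3. An excess over the simulation was thus seen over all genes too, though relative to the simulated means it was larger among induced genes. The simulated noise came from the residuals of the additive fit, which are themselves differences between the genotypes' responses. The simulation is therefore no independent reference for these counts.

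The list medians of the response difference at 4 h were -0.58 for interferon-stimulated genes (percentile 0.255 among lists matched on induction), -0.38 for cytokines (0.73), -0.29 for chemokines (2.14) and -0.61 for 7 genes described as dependent on the NF-kB cofactor IkB-zeta (2.13). They were -0.22 for SWI/SNF-dependent (33.1) and -0.38 for SWI/SNF-independent LPS genes (10.8). The median over all genes was 0.12, and -0.15 with arrays centred, so the lists are also given relative to it: -0.69 for interferon-stimulated genes, -0.50 for cytokines, -0.41 for chemokines, -0.73 for IkB-zeta-dependent, -0.33 for SWI/SNF-dependent and -0.50 for SWI/SNF-independent genes, and -0.15 for the NF-kB list. These lists share members. At 2 h cytokines and chemokines stood at 0.0015 (63.8) and 0.016 (47.3), interferon-stimulated genes at -0.17 (0.075), IkB-zeta-dependent genes at -0.74 (0.125), and SWI/SNF-dependent and SWI/SNF-independent genes at -0.47 (1.17) and -0.24 (16.9), where the median over all genes was 0.091. Of the 21 function lists, 4 lay below the 2.5th percentile at 2 h and 5 at 4 h, and SWI/SNF subunits lay at the high end at 2 h (98.3). With the higher expression floor the SWI/SNF-dependent median turned to 0.24 at 2 h and 0.35 at 4 h, and with no floor it was -0.11 at 2 h. The chemokine median at 4 h was -0.11 with no floor and -0.48 with the higher floor, and with probe sets averaged cytokines stood at -0.25 and SWI/SNF-independent genes at -0.23.

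The limma interaction passed for 4 genes, Ereg (-1.94, adjusted p = 0.0263), Orly (-1.93, adjusted p = 0.0263), Rbms3 (-1.78, adjusted p = 0.0447) and Mavs (1.75, adjusted p = 0.0461). The unadjusted p was under 0.05 for 1739 genes. Il6 had an interaction of -1.57 (adjusted p = 0.0516). With no floor, with the higher floor and without cross-hybridising probe sets 0 genes passed, while 20 were higher and 42 lower with quantile normalization again, and 155 and 101 with eBayes set to trend and robust. In simulated data with 100 genes changed at each size, the interaction gave a mean of 21.7 false calls. It recovered 41.5% of the genes changed by a log2 of 1 and 99.9% of those changed by 2. The false calls were thus a larger share of all calls than the 0.05 that the adjustment aims at. The adjusted p of the interaction was too lenient in that simulation. Such changed genes also loosen the adjusted threshold, so this mean does not say how many of the 4 calls are false.

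**Figure D4:**
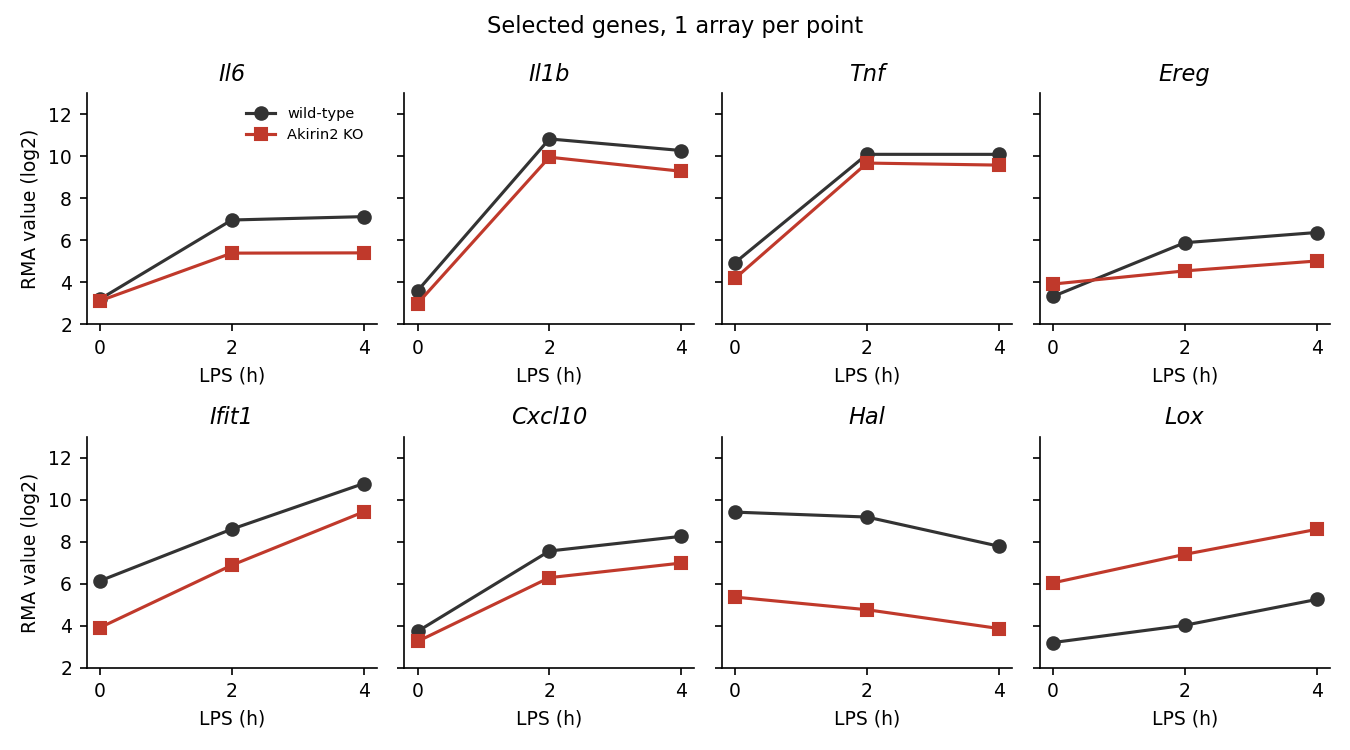
RMA values (log2) of 8 named genes against hours of LPS, 1 array per point, for wild-type (circles) and Akirin2 KO (squares). Il6 reaches 7.13 in wild-type and 5.41 in KO at 4 h, while Hal and Lox differ at every time.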

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

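Of the tests in this part, those of other splits of the arrays, of genes near the targeted loci, of the overall response, of macrophage markers and all those on falling genes were chosen only after the result was seen.

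The genotype by stimulation test passed for 4 genes. It passed for 0 with no floor, with the higher floor or without cross-hybridising probe sets and for 1 with probe sets averaged, but for 20 higher and 42 lower with quantile normalization again, 155 and 101 with eBayes set to trend and robust, and 44 and 36 at an adjusted p of 0.1. Simulated data with 100 genes changed at each size gave a mean of 21.7 false calls. Those changed genes loosen the adjusted threshold, so the number does not say how many of the 4 are false. Ereg had an interaction of -1.94, with values of 3.33, 5.89 and 6.38 in wild-type and 3.92, 4.55 and 5.02 in KO. Orly had -1.93, and its KO value was 7.81 at 0 h against 6.20 to 6.63 on the other 5 arrays. Rbms3 had -1.78 and Mavs 1.75. The 0 h array of KO carried hybridisation spikes (bioB and bioC) 0.69 above wild-type at 0 h. Among 6130 probe sets without a single gene name, 2 were at least 2-fold higher and 3 at least 2-fold lower in KO at all 3 times.

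The first pattern is the set of 265 genes that limma called between genotypes. Splitting the 6 arrays into 3 and 3 allows 10 splits, which are too few for a share under 0.05; 1 of the 10, the real one, called 265 genes and the highest other called 0. Flanking DNA from the strain of the targeted stem cells was tested only within the 100 nearest annotated genes on either side of Akirin2 or Lyz2. Of the called genes 1.14%, 3 of 264, lie there, against 0.714% of all genes tested. DNA within this window thus does not account for most of the set. Longer flanking segments, possible on a mixed background, were not tested. Variants under single probe sets stay open: of 143 called genes with another probe set above the floor, 37.1% differed the same way by at least 0.5 of the difference, and 120 had the same sign. Loss of Akirin2, other strain segments and differences between mice cannot be told apart by this design. The 3 measured strain-variable genes had a median of 0.37 (percentile 99.2) and 0 calls. No direction was set for each of them, so this median shows neither a strain difference nor its absence.

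The next pattern is the lower level of interferon-stimulated genes in KO. A weaker LPS response overall does not account for all of it, but may account for a part. The list's median response difference at 4 h was -0.58, at percentile 0.255 among lists matched on induction. Those matched lists stood at -0.21 themselves, against 0.12 over all genes. The matching was rough, with a smallest pool of 11 genes. Rescaling the deposited values did not remove the lower level of the list: its median at 4 h was at most -1.02 under renormalization and centring. The deposited arrays were already normalized and these settings change them little, so an effect of the original scaling is not excluded. Macrophage markers as a set differed by -0.096 at 4 h (-0.20 with arrays centred), less than the interferon list. Their median still lay low, at percentile 2.12 among random lists, and 3 of 17, Fcgr1, C1qa and C1qc, fell over the 3 times. The genotype remains a candidate explanation, as a hypothesis, beside strain background, the lower mesothelial and fibroblast markers and the higher 3′ to 5′ difference of Actb in KO (4.64, 4.50 and 4.36 against 4.22, 4.16 and 4.09), none of which was tested, and 14 of 21 function lists stood low. The Gapdh difference was 4.34, 4.52 and 4.44 in KO against 4.33, 4.33 and 4.42 in wild-type.

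The last pattern is the smaller number of genes lower at 4 h in KO (336) than in wild-type (646). Scaling may account for some or all of it and stays open, since the ratio of wild-type to KO counts was 0.939 with each array centred but 1.33 with quantile normalization again (582 and 436). Relative to the median of all genes, falling genes responded 19.0% less and rising genes 12.3% less in KO, 6.61 percentage points apart, as a general compression would give. Without that reference the median response differences at 4 h were less even, 0.39 for falling and -0.087 for rising genes. The difference at 0 h made up 27.1% of the response difference of falling genes. No separate effect of genotype on falling genes is shown.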

How the results depend on the processing

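The 4607 genes below the floor were not interpreted, and no condition had a replicate. No paired analysis was possible because the conditions, with 1 array each, share fewer than 2 replicate numbers; this concerns replicate numbers alone, and the additive fit compares the genotypes within each time. Of the counts, list medians and Akirin2 levels under the alternatives, 505 held (counts within 1.5 times, medians within the spread of random lists), 200 moved and 6 list medians reversed. The 1 lost call was that of Akirin2 by its other probe set. A list median counts as reversed only if it lay more than 2 random spreads from 0; whatever its size, the sign changed in 43 of 492 list medians under the alternatives, 17 of them with arrays centred. The setting with no floor says nothing about the 2-fold counts, since those genes differed by at most 0.81 between any 2 arrays. Of 1234 values of named genes, 1153 held, 58 moved, 20 lost their call and 3 reversed. Fewer or more genes past looser and stricter size rules follow from their construction, and centring moves the response difference of every gene at 4 h by the same amount, from a median of 0.12 to -0.15. Choosing induced genes in 1 genotype favours a larger response in that genotype, also by construction. For the other changes the cause was not tested.

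LPS response in wild-type, lower at 2 h: the count of 297 was 151 with probe sets averaged, 191 centred, 1252 at 1.5-fold and 49 at 3-fold. LPS response in wild-type, lower at 4 h: the count of 646 was 357 with probe sets averaged, 428 centred, 1808 at 1.5-fold and 171 at 3-fold. LPS response in Akirin2 KO, higher at 2 h: the count of 332 was 217 with probe sets averaged, 887 at 1.5-fold and 129 at 3-fold. LPS response in Akirin2 KO, lower at 2 h: the count of 123 was 49 with probe sets averaged, 670 at 1.5-fold and 18 at 3-fold. LPS response in Akirin2 KO, lower at 4 h: the count of 336 was 152 with probe sets averaged, 1033 at 1.5-fold and 73 at 3-fold. Akirin2 KO against wild-type at 0 h, higher: the count of 106 was 36 with probe sets averaged, 196 centred, 489 at 1.5-fold and 14 at 3-fold. Akirin2 KO against wild-type at 0 h, lower: the count of 156 was 66 with probe sets averaged, 85 centred, 900 at 1.5-fold and 12 at 3-fold. Akirin2 KO against wild-type at 2 h, higher: the count of 66 was 37 with probe sets averaged, 420 at 1.5-fold and 17 at 3-fold. Akirin2 KO against wild-type at 2 h, lower: the count of 63 was 37 with probe sets averaged, 369 at 1.5-fold and 9 at 3-fold. Akirin2 KO against wild-type at 4 h, higher: the count of 113 was 50 with probe sets averaged, 75 centred, 638 at 1.5-fold and 16 at 3-fold. Akirin2 KO against wild-type at 4 h, lower: the count of 84 was 52 with probe sets averaged, 451 at 1.5-fold and 14 at 3-fold. LPS response difference at 2 h, less induced in KO: the count of 14 was 8 with probe sets averaged, 65 at 1.5-fold, 2 at 3-fold and 9 chosen in KO. LPS response difference at 2 h, more induced in KO: the count of 4 was 1 with probe sets averaged, 41 at 1.5-fold, 0 at 3-fold, 2 chosen in wild-type and 13 chosen in KO. LPS response difference at 4 h, less induced in KO: the count of 35 was 23 with probe sets averaged, 66 centred, 131 at 1.5-fold and 2 at 3-fold. LPS response difference at 4 h, more induced in KO: the count of 10 was 6 centred, 106 at 1.5-fold, 1 at 3-fold, 6 chosen in wild-type and 44 chosen in KO. LPS response in wild-type, higher at 2 h: the count of 307 was 731 at 1.5-fold and 142 at 3-fold. LPS response in wild-type, higher at 4 h: the count of 505 was 1109 at 1.5-fold and 245 at 3-fold. LPS response in Akirin2 KO, higher at 4 h: the count of 553 was 1388 at 1.5-fold and 223 at 3-fold. Genotype by stimulation interaction, higher: the count of 1 was 0 with no floor, 0 with the higher floor, 0 with probe sets averaged, 0 without cross-hybridising probe sets, 20 renormalized, 155 with trend and robust and 44 at an adjusted p of 0.1. Genotype by stimulation interaction, lower: the count of 3 was 0 with no floor, 0 with the higher floor, 1 with probe sets averaged, 0 without cross-hybridising probe sets, 42 renormalized, 101 with trend and robust and 36 at an adjusted p of 0.1. Genotype effect over the 3 times, lower: the count of 144 was 95 with probe sets averaged, 464 with trend and robust, 288 at an adjusted p of 0.1, 294 without the 0 h arrays and 86 without the 2 h arrays. Genotype effect over the 3 times, higher: the count of 121 was 419 with trend and robust, 244 at an adjusted p of 0.1, 370 without the 0 h arrays and 72 without the 2 h arrays. LPS effect over both genotypes at 2 h, higher: the count of 538 was 841 with trend and robust. LPS effect over both genotypes at 2 h, lower: the count of 393 was 828 with trend and robust and 683 at an adjusted p of 0.1. LPS effect over both genotypes at 4 h, higher: the count of 1055 was 476 with the LPS times together. LPS effect over both genotypes at 4 h, lower: the count of 1034 was 342 with the LPS times together.

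For list medians of the difference between genotypes, values under the alternatives were as follows. Proinflammatory cytokines, over the 3 times (-0.20), gave -0.33 with the higher floor. Proinflammatory cytokines, response difference at 2 h (0.0015), gave -0.11 renormalized and -0.16 centred. Proinflammatory cytokines, response difference at 4 h (-0.38), gave -0.25 with probe sets averaged and -0.65 centred. Chemokines, over the 3 times (-0.20), gave -0.29 with the higher floor. Chemokines, response difference at 2 h (0.016), gave -0.14 centred. Chemokines, response difference at 4 h (-0.29), gave -0.11 with no floor, -0.48 with the higher floor, -0.38 renormalized and -0.56 centred. NF-kB subunits and feedback regulators, response difference at 2 h (-0.067), gave -0.17 renormalized and -0.23 centred. NF-kB subunits and feedback regulators, response difference at 4 h (-0.031), gave -0.30 centred. Interferon-stimulated genes, over the 3 times (-0.72), gave -0.63 with probe sets averaged. Interferon-stimulated genes, response difference at 2 h (-0.17), gave -0.33 centred. Interferon-stimulated genes, response difference at 4 h (-0.58), gave -0.84 centred. Interferon-stimulated genes, at 0 h (-0.37), gave -0.29 with probe sets averaged, -0.30 renormalized and -0.21 centred. Interferon-stimulated genes, at 2 h (-0.59), gave -0.65 with the higher floor. Interferon-stimulated genes, at 4 h (-1.03), gave -1.15 with the higher floor, -1.10 without cross-hybridising probe sets and -1.14 centred. Immediate-early genes, over the 3 times (-0.094), gave 0.10 with the higher floor. Immediate-early genes, response difference at 2 h (0.24), gave 0.36 with the higher floor and 0.079 centred. Immediate-early genes, response difference at 4 h (0.30), gave 0.39 with the higher floor and 0.037 centred. SWI/SNF-dependent LPS genes, over the 3 times (-0.49), gave -0.33 with no floor. SWI/SNF-dependent LPS genes, response difference at 2 h (-0.47), gave -0.11 with no floor, 0.24 with the higher floor and -0.63 centred. SWI/SNF-dependent LPS genes, response difference at 4 h (-0.22), gave 0.35 with the higher floor and -0.48 centred. SWI/SNF-independent LPS genes, response difference at 2 h (-0.24), gave -0.40 centred. SWI/SNF-independent LPS genes, response difference at 4 h (-0.38), gave -0.23 with probe sets averaged and -0.65 centred. IkB-zeta-dependent LPS genes, response difference at 4 h (-0.61), gave -0.88 centred. Antimicrobial and effector enzymes, response difference at 2 h (0.13), gave 0.24 with no floor, 0.25 with the higher floor and -0.033 centred. Antimicrobial and effector enzymes, response difference at 4 h (0.082), gave -0.064 with no floor, 0.29 with the higher floor and -0.18 centred. TLR signalling components, over the 3 times (-0.22), gave -0.11 with probe sets averaged. TLR signalling components, response difference at 2 h (-0.0074), gave 0.076 without cross-hybridising probe sets, -0.10 renormalized and -0.17 centred. TLR signalling components, response difference at 4 h (-0.094), gave -0.24 renormalized and -0.36 centred. SWI/SNF subunits, response difference at 2 h (0.28), gave 0.11 with probe sets averaged, 0.20 without cross-hybridising probe sets, 0.15 renormalized and 0.12 centred. SWI/SNF subunits, response difference at 4 h (0.15), gave 0.045 with probe sets averaged and -0.12 centred. Proteasome core and regulatory subunits, response difference at 2 h (-0.033), gave 0.038 with probe sets averaged and -0.19 centred. Proteasome core and regulatory subunits, response difference at 4 h (0.0093), gave 0.073 with probe sets averaged, 0.12 without cross-hybridising probe sets and -0.26 centred. P53 target genes, response difference at 2 h (0.15), gave -0.0098 centred. P53 target genes, response difference at 4 h (0.11), gave -0.16 centred. Cell cycle, over the 3 times (-0.19), gave -0.25 with the higher floor. Cell cycle, response difference at 2 h (0.26), gave 0.16 with the higher floor, 0.14 with probe sets averaged and 0.10 centred. Cell cycle, response difference at 4 h (0.23), gave -0.041 centred. ER stress, over the 3 times (-0.078), gave -0.15 with the higher floor. ER stress, response difference at 2 h (0.12), gave -0.040 centred. ER stress, response difference at 4 h (0.27), gave 0.38 with probe sets averaged and 0.0033 centred. Heat shock proteins, response difference at 2 h (0.16), gave 0.085 with probe sets averaged, 0.025 renormalized and 0.00075 centred. Heat shock proteins, response difference at 4 h (0.31), gave 0.21 renormalized and 0.048 centred. NRF2 targets, response difference at 2 h (0.12), gave -0.017 with probe sets averaged, 0.0078 without cross-hybridising probe sets and -0.039 centred. NRF2 targets, response difference at 4 h (0.26), gave -0.0029 with probe sets averaged, 0.066 without cross-hybridising probe sets and -0.0062 centred. Antigen presentation and co-stimulation, over the 3 times (-0.29), gave -0.22 with probe sets averaged and -0.34 without cross-hybridising probe sets. Antigen presentation and co-stimulation, response difference at 2 h (0.15), gave -0.011 centred. Antigen presentation and co-stimulation, response difference at 4 h (0.094), gave 0.010 renormalized and -0.17 centred. Alternative activation, response difference at 2 h (0.15), gave -0.011 centred. Alternative activation, response difference at 4 h (0.28), gave 0.40 with the higher floor and 0.0096 centred. Glycolysis and hypoxia response, response difference at 2 h (0.16), gave 0.074 with probe sets averaged, 0.087 without cross-hybridising probe sets, 0.10 renormalized and 0.0013 centred. Glycolysis and hypoxia response, response difference at 4 h (0.22), gave 0.11 renormalized and -0.050 centred. Cholesterol synthesis and efflux, over the 3 times (-0.41), gave -0.48 with the higher floor. Cholesterol synthesis and efflux, response difference at 2 h (0.25), gave 0.17 with probe sets averaged and 0.090 centred. Cholesterol synthesis and efflux, response difference at 4 h (0.090), gave -0.070 without cross-hybridising probe sets and -0.18 centred. Macrophages, over the 3 times (-0.12), gave -0.22 without cross-hybridising probe sets. Macrophages, at 4 h (-0.10), gave -0.20 centred. Resident large peritoneal macrophages, over the 3 times (-0.21), gave -0.30 with the higher floor. Resident large peritoneal macrophages, at 0 h (-0.61), gave -0.46 with probe sets averaged, -0.48 renormalized and -0.45 centred. Neutrophils, over the 3 times (-0.19), gave -0.061 with no floor and -0.33 with the higher floor. T and NK cells, over the 3 times (-0.020), gave 1.19 with the higher floor. Mast cells, over the 3 times (0.032), gave -0.17 with the higher floor. Mesothelial cells and fibroblasts, over the 3 times (-0.62), gave -0.32 with probe sets averaged. Mesothelial cells and fibroblasts, at 4 h (-0.46), gave -0.72 with the higher floor and -0.25 with probe sets averaged.

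Akirin2 differed by -2.20 and by -0.027 by the other probe set. Xaf1 between genotypes at 4 h turned from -1.82 to 1.09 with probe sets averaged. Xaf1 between genotypes over the 3 times turned from -1.37 to 0.46 with probe sets averaged. Asph at 2 h of LPS turned from -2.02 to 0.047 without cross-hybridising probe sets.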

Other observations

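The test in this part was chosen before its result was seen.

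Several gene groups had few or no members that passed limma between genotypes. Proteasome subunits had 0 calls among 32 measured and a median over the 3 times of -0.054, and p53 targets had 0 among 15 and a median of 0.057; adjusted over the list alone each had 0. Glycolysis genes had 0 calls (adjusted over the list alone, 1 rose and 1 fell) and a median of -0.038. SWI/SNF subunits had a median of 0.011, and Smarca2 rose by 0.92 (adjusted p = 0.0215). Heat shock genes had a median of -0.049, and among them Hsph1 rose by 0.96 and Hspa1b fell by 0.89. The median of ER stress genes was -0.078, where Asns fell by 1.15, and that of immediate-early genes was -0.094. With the higher floor these were -0.15 and 0.10.

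Other groups stood lower in KO with few single calls, beside mesothelial and fibroblast markers at -0.62 and an Actb 3′ to 5′ difference of 4.64, 4.50 and 4.36 in KO against 4.22, 4.16 and 4.09 in wild-type. For Gapdh this difference was 4.34, 4.52 and 4.44 in KO against 4.33, 4.33 and 4.42. NRF2 targets had 0 calls, 5 lower when adjusted over the list alone, and a median of -0.35, below all random lists. Alternative activation genes had a median of -0.34, with Ccl24 called and 4 lower over the list alone. Antimicrobial enzymes stood at -0.34 with Slpi (-1.10) called and 2 lower over the list alone. Cell cycle genes stood at -0.19 with Mcm7 (-0.75) called and 6 lower over the list alone, and antigen presentation genes at -0.29. The SWI/SNF-dependent, SWI/SNF-independent and IkB-zeta-dependent LPS genes had medians of -0.49, -0.23 and -0.49, with 0, 2 and 0 calls and 4, 3 and 5 lower over the list alone.

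A hypothesis was that genes induced late are lower in KO at 4 h even outside the interferon list. Of 454 induced genes outside that list, 102 were at least 2-fold higher at 4 h than at 2 h on average of both genotypes. Their median difference between genotypes at 4 h was -0.45, against -0.27 for the other induced genes, at percentile 0.07 among random sets of induced genes. At 4 h mesothelial and fibroblast markers stood at -0.46, and the Actb 3′ to 5′ difference was 4.36 in KO against 4.09 in wild-type. That of Gapdh was nearly equal at 4 h, 4.44 in KO against 4.42 in wild-type. The random sets were not matched on size of induction or on expression, and the difference at 4 h includes any at 0 h. The test therefore cannot tell a lower late response in KO from a general compression or a difference at 0 h. Interferon-responsive genes outside the list may also contribute, and genes are not independent replicates.

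Of 11 measured neighbours of Akirin2 on its chromosome Rragd fell by 0.82, and the median was 0.038. The 3 measured genes picked as varying between C57BL/6 and 129 had a median of 0.37 at percentile 99.2, with 0 calls over all genes and 1 higher over the list alone. No direction was set for each of these genes, so their median does not show a strain difference. The 4 sex-linked genes had a median of 0.18 and 0 calls. Of the 3 genes of the targeted alleles list Akirin2 passed.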
